A study of Homo sapiens with 6 samples.

How the data were processed

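Gene expression was measured in 6 cultures of stably transfected MCF10A cells, 3 with a non-targeting shRNA and 3 with an shRNA against FRY. Per the labels' protocols, the cells were selected with puromycin and 1 stable clone was kept for each construct. They grew in mammary epithelial medium with 20 ng/ml epidermal growth factor, 10 ug/ml insulin, 5 ug/ml hydrocortisone and pituitary extract, and total RNA was taken at 70% confluence. Per the labels' protocols, 40 ng of total RNA per sample was amplified into cDNA, fragmented and labelled with biotin. Each sample was on an array of its own with 1 colour. Short or degraded RNA lowers 5' probe sets relative to 3' ones, so control probe sets for RNA length were examined.

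The deposited values are on the log2 scale and come from RMA, per the submitters' processing notes; the version, the settings and the software that ran it are not given in the sources used here. RMA as usually run subtracts background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a probe set, and it compresses fold changes of dim probe sets. The medians of the 6 samples lay between 3.02 and 3.06. A change shared by all genes could not be seen after such a normalization. The values were used as deposited. No scanner files were used here.

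Probe sets were named through a platform annotation, which can be old, and symbols were updated through Entrez IDs to the RefSeq genes of GRCh38.p14. Of the 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none listed. For 41037 of those with 1 symbol the Entrez ID was in the RefSeq table, and for 54 the old symbol was kept. Probe sets with several symbols or none were left out of the gene-level tests. No genome build belongs to these values, so no coordinates are given, and the RefSeq table served for names and for the order of neighbouring genes.

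Each of 19775 genes was represented by the probe set with the highest mean over all 6 samples among those naming that gene alone. The groups were compared, as shFRY minus control, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with no trend, no robust option and no filter on dim probe sets), which left 4 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg over all genes. The threshold was an adjusted p of 0.05, and a fold change of at least 2 was counted beside it. FRY and FRYL probe sets were tested in the same kind of fit over the 54613 probe sets other than controls. The control probe sets were tested in such a fit over all 54675 probe sets. Two-sided exact permutation tests of 3 against 3 samples cannot give a p under 0.1. The group labels come from the sample titles.

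The comparison, its test, the gene lists, the naming rule and the alternatives other than the beta-actin covariate were fixed before the data were examined. Tests of technical explanations and of gene families were chosen later. The 35 lists were written from textbook knowledge of mammary epithelium and of FRY, with markers of fibroblasts, immune cells, endothelium and adipocytes as lists of other cell types. They hold 665 genes, 623 of them measured and 33 in more than 1 list. Lists were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the 35 lists, and again with a correlation estimated per list. With an estimated correlation camera also has only the 4 residual degrees of freedom, so p-values rise there even where the estimate is low. Members were counted as rising or falling after adjustment over all genes and adjusted over the list alone. Named genes are FRY, the 10 largest rises and the 10 largest falls by log2 fold change among genes past the threshold whose 3 shFRY samples all lie on one side of the 3 control samples, and, for each list described, up to 4 members past the threshold with the largest absolute log2 fold change; where no member passes, up to 2 with the smallest p. A gene chosen outside this rule is said to be so where it appears.

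The scripts were tested on simulated data made from the means and spreads of these samples. With 200 of 19775 genes changed, the comparison of shFRY with control recovered 34.3%, 71.6% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, and 8 of its 145 calls were of unchanged genes. With no gene changed among 19775 it called 0 genes and 0 lists. Genes were drawn independently in these data, whereas the replication list, for example, had an estimated correlation of 0.43 in the real samples. The 0 lists therefore do not bear on lists of correlated genes. The recovered shares belong to 200 changed genes, far fewer than were called in the real samples.

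The alternatives were centring each sample on the median, another quantile normalization, eBayes with trend and robust options, the upper part of probe sets by mean, the mean of a gene's probe sets, probe sets other than those ending in _x_at and _s_at, array weights, the replicate number as a block and leaving out each sample. All probe sets in place of 1 per gene, an adjusted p of 0.01, treat against a fold of 1.2, and list medians against 10000 random lists of the same size matched on mean expression were also run. The beta-actin 3' minus 5' difference as a covariate was added after the data were seen. Arrays give no counts, so precision comes from the 3 samples per group and from the signal over background.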

Results

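The effect of an shRNA against FRY on gene expression was examined in MCF10A, a non-tumorigenic human mammary epithelial cell line. FRY, the human homologue of the Drosophila furry gene, encodes a large microtubule-associated protein that binds NDR kinases. Total RNA came from 2 kinds of stably transfected cells: 3 samples of a clone carrying an shRNA directed at FRY (shFRY) and 3 samples of a clone carrying a non-targeting shRNA (control). Each construct was represented by 1 selected clone, and the samples of a clone differed in passage number, so the p-values measure only the spread between these samples. Biotin-labelled cDNA was hybridised to 1-colour arrays with 54675 probe sets, and the deposited log2 values had medians between 3.02 and 3.06 in the 6 samples. Samples of a group correlated at r = 0.992 to 0.995 across probe sets, and samples of different groups at r = 0.972 to 0.978. The number of arrays limits the precision: the median SD of a gene between samples was 0.13 in the control group and 0.15 in the shFRY group (log2, n = 3 each).

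FRY signal was lower in the shFRY samples than in the control samples at each of its 4 probe sets, and 1 of them passed the threshold. Probe set 204072_s_at fell by 0.75 on the log2 scale (SE 0.19, limma adjusted p = 0.0223), from 3.86 ± 0.34 in the control samples to 3.11 ± 0.22 in the shFRY samples (SD, n = 3 each). This is a reduction of 40.6% with a 95% confidence interval of 19.7% to 56.1%. The log2 differences at 1555904_at, 214318_s_at and 214319_at were -0.49, -0.32 and -0.49, with limma adjusted p-values of 0.0576, 0.103 and 0.203. In the comparison with 1 probe set per gene, FRY was represented by 214319_at and did not pass (limma adjusted p = 0.181, 95% confidence interval -1.05 to 0.08). All shFRY samples lay below all control samples at every FRY probe set except 214319_at, where they overlapped (two-sided exact permutation p = 0.1, the smallest that 3 against 3 samples can give, and 0.2 at 214319_at). The labels put FRY in the selected clone about 60% below its level in MCF10A cells, a log2 difference of -1.32. The nearest bound of any FRY probe set was 56.1%. The 2 values have different references, since the arrays compare shFRY with the control clone. How the stated value was measured is not given in the sources used here, so the bound does not contradict it. FRY was a dim gene on this array, its probe set means lying between the percentiles 47.3 and 68.4 of all probe sets. Its paralog FRYL was higher in shFRY at 2 of its 6 probe sets, 1554260_a_at (0.56, limma adjusted p = 0.0220) and 212548_s_at (0.61, limma adjusted p = 0.0300). The call at 204072_s_at was lost without control sample 1 or 3 or without shFRY sample 1 or 3, with limma adjusted p-values of 0.0650, 0.0539, 0.0712 and 0.0502, and with the beta-actin covariate described with the gene counts, where it was -0.38 (SE 0.35). With the replicate number as a block it was lost as well (0.0522), while 1555904_at (0.0263) and 214319_at (0.0365) passed.

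**Figure D1:**
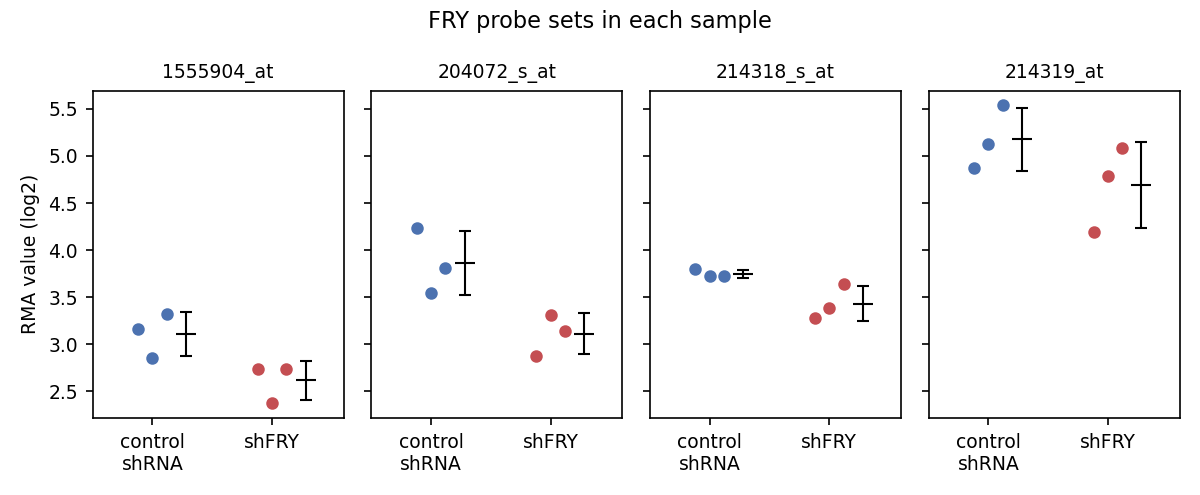
RMA values (log2) of the 4 FRY probe sets in each control and shFRY sample; points are samples, and the bar with whiskers is the mean ± SD (n = 3). The shFRY samples lie below the control samples at 3 of the probe sets and overlap them at 214319_at.

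Inflammatory chemokine genes were among the largest rises in shFRY cells. CXCL1, a neutrophil chemokine, rose from 3.297 ± 0.22 to 10.79 ± 0.21 (SD, n = 3 each), a log2 fold change of 7.49 (SE 0.15, limma adjusted p = 9.91e-08). It was followed by its relatives CXCL3 (7.28), CXCL2 (6.11) and CXCL8 (5.54), which encodes interleukin-8. The other genes among the 10 largest rises were the decoy receptor gene IL13RA2 (6.08), the NF-kB inhibitor gene TNIP3 (6.05), PID1 (5.83), IRAK2, a kinase of interleukin-1 signalling (5.44), the peptide hormone gene SPX (5.09) and CYP24A1, which encodes the vitamin D 24-hydroxylase (5.08). The control signals of several of these genes, such as CXCL3 (3.43), TNIP3 (2.63), PID1 (2.40) and IL13RA2 (1.62), lay near or below the median of all probe sets (3.04). Their fold changes may therefore be lower limits, and their order is not fixed. AGR2, a protein disulfide isomerase of mucus-secreting cells, had the largest fall, from 10.77 ± 0.26 to 5.67 ± 0.42 (SD, n = 3 each; log2 fold change -5.10, SE 0.22, limma adjusted p = 3.77e-06). PDK4 (-4.31), the mucin gene MUC5AC (-4.14), LUM (-3.94), CCNE2, which encodes cyclin E2 (-3.88), CFAP95 (-3.87), SERTAD4 (-3.84), FAM111B (-3.72), HSD11B2 (-3.70) and GCNT3, which builds mucin O-glycans (-3.51), completed the 10 largest falls. Signals in shFRY below the median of all probe sets, as for PDK4 (2.58), HSD11B2 (2.13) and LUM (1.22), mean that such falls may be lower limits too. The fall of LUM rests on 1 of its 2 probe sets: with probe sets of the _s_at and _x_at kind left out, its difference was -0.02.

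**Figure D2:**
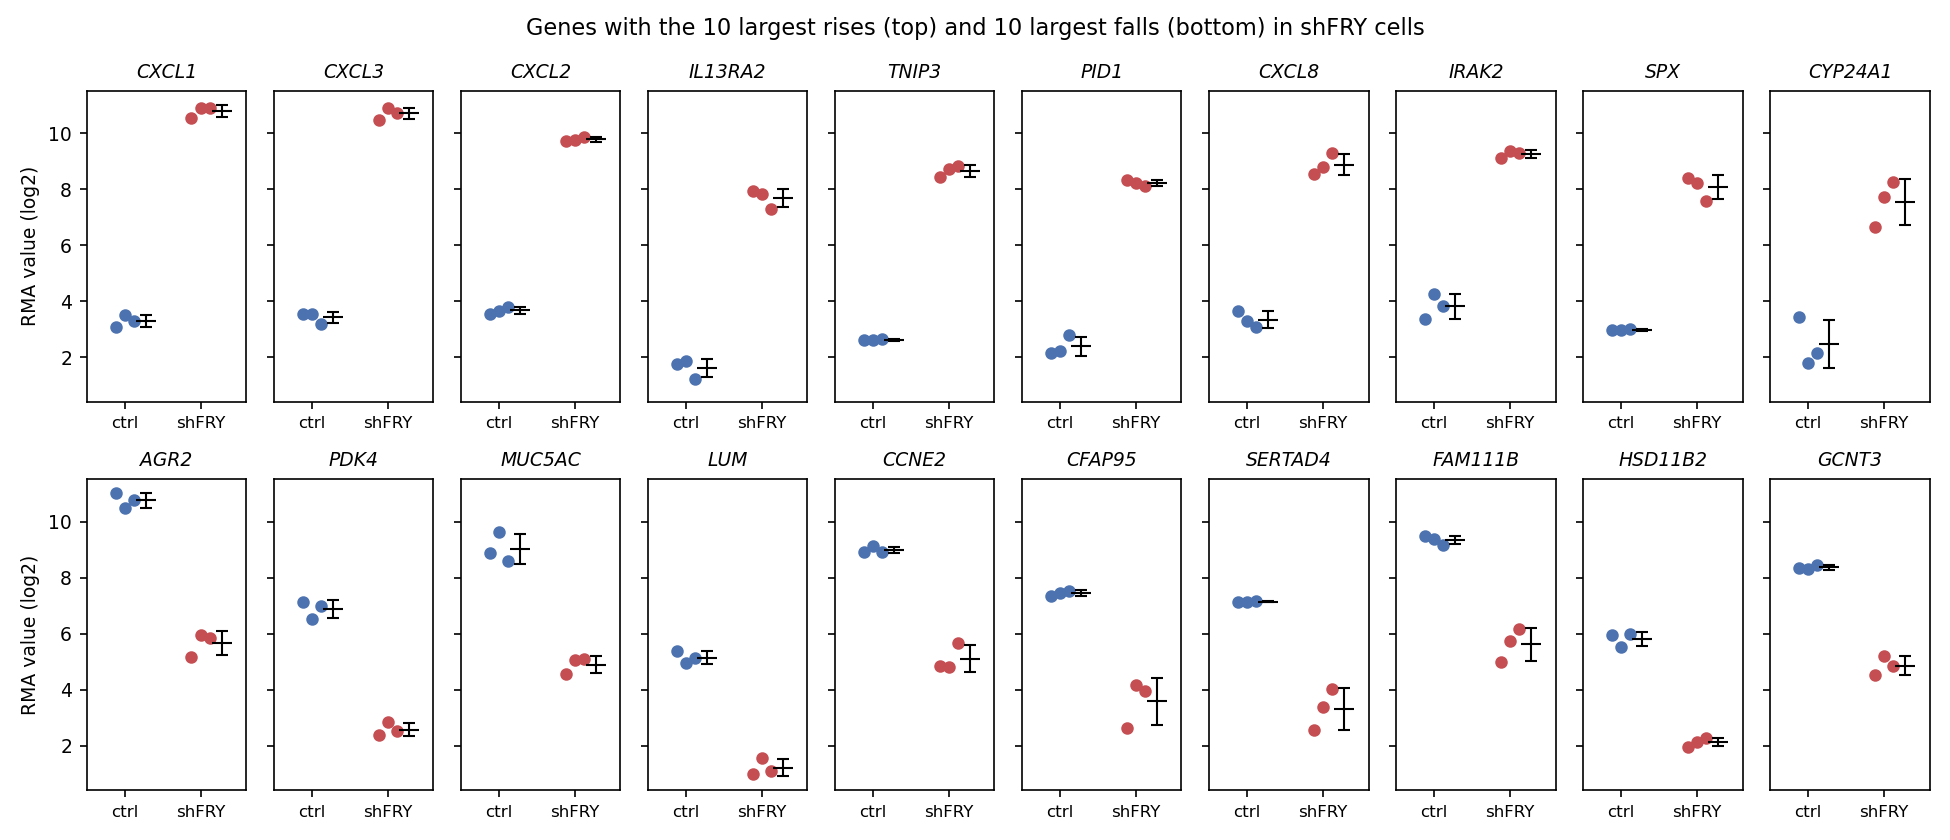
RMA values (log2) of the genes with the 10 largest rises (top) and 10 largest falls (bottom) in shFRY cells, by sample; ctrl is the control shRNA, points are samples, and the bar with whiskers is the mean ± SD (n = 3). In every panel the 3 shFRY samples lie apart from the 3 control samples, as the rule for choosing these genes requires.

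Over all 19775 genes tested, 5889 (29.8%) passed an adjusted p of 0.05 in limma, 2718 of them higher and 3171 lower in shFRY. A change of at least 2-fold was found for 1484 of them, 677 higher and 807 lower, and a change of at least 8-fold for 97, of which 74 were higher and 23 lower. The groups did not overlap for 44.2% of genes, against the 10% that chance gives for 3 against 3 samples. Of the 3866 called genes with several probe sets, 2190 had another probe set called in the same direction and 101 had one called in the other direction. The beta-actin control probe sets, a measure of RNA length and amplification, had a 3' minus 5' difference of 2.52 ± 0.19 in the control samples and 2.87 ± 0.03 in the shFRY samples (log2, SD, n = 3 each; two-sided exact permutation p = 0.1), so this measure moved with the group and with every gene group described here. The GAPDH difference was -0.09 ± 0.01 and -0.07 ± 0.03 (SD, n = 3 each; exact permutation p = 0.4). Other control probe sets also moved with the group. The GAPDH 3' and 5' signals were lower by 0.44 and 0.46 in shFRY, and the hybridisation spikes bioB and bioC were higher by 0.49 and 0.46. None of these 4 overlapped between the groups (exact permutation p = 0.1). All kept their directions under median centring and another quantile normalization, which change these already normalized values little. The spikes bioD and cre were higher by 0.21 and 0.15 with overlap (exact permutation p = 0.3). Of the 62 control probe sets, 10 passed the threshold. With the beta-actin difference of each sample as a covariate, a setting chosen after the data were seen, 1026 genes passed: the median absolute log2 fold change of the 5889 genes was 0.67 without and 0.65 with it, while their median SE went from 0.12 to 0.23.

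**Figure D3:**
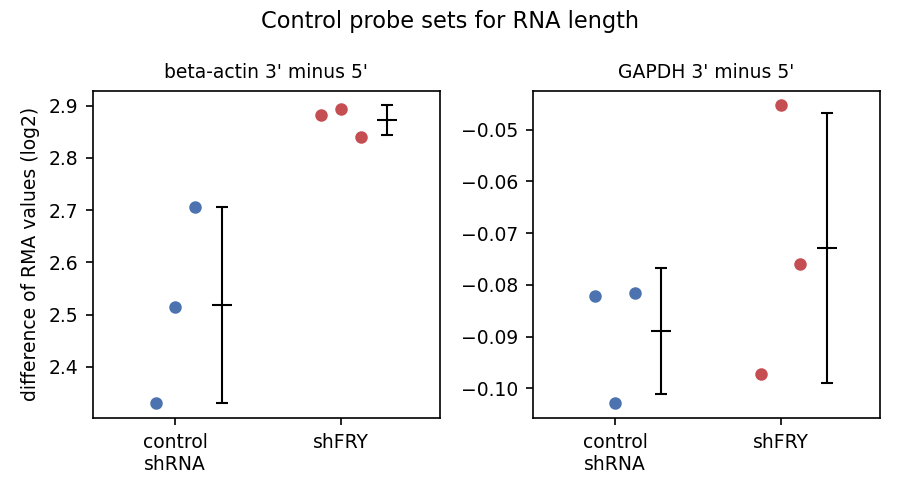
Difference between the 3' and 5' control probe sets (log2) for beta-actin and GAPDH in each sample; points are samples, and the bar with whiskers is the mean ± SD (n = 3). The beta-actin difference is higher in all 3 shFRY samples than in the control samples, and the GAPDH differences overlap.

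Of the 21 measured genes in the list of inflammatory cytokines and NF-kB targets, 16 rose and 0 fell, with a median log2 fold change of 1.997 (camera adjusted p = 1.26e-13). The same 16 and 0 were found adjusted over the list alone, and this was the only list of the 35 to pass with a correlation estimated per list (adjusted p = 0.0348 with an estimated correlation). CXCL1, CXCL3, CXCL2 and CXCL8 led it. Genes of the unfolded protein and ATF4 response, which is switched on by endoplasmic reticulum stress and amino acid shortage, also rose together: 17 of 20 rose and 0 fell, with the same numbers adjusted over the list alone and a median of 1.38 (camera adjusted p = 1.24e-11; adjusted p = 0.154 with an estimated correlation). Its leading members were the transcription factor genes DDIT3 (3.62) and ATF3 (3.53), TRIB3 (3.49) and SESN2 (3.23), a stress-induced regulator of mTORC1. Both groups rose in the samples whose beta-actin 3' minus 5' difference was higher by 0.35.

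DNA replication and S phase genes were lower in shFRY cells, and mitotic genes were lower by a smaller amount. Of 29 measured replication genes, 23 fell and 0 rose, 24 and 0 adjusted over the list alone, with a median log2 fold change of -1.20 (camera adjusted p = 7.03e-13; adjusted p = 0.180 with an estimated correlation). The cyclin E genes CCNE2 (-3.88) and CCNE1 (-2.80), GINS1 of the replicative helicase (-1.83) and the polymerase clamp gene PCNA (-1.77) fell most. Of 29 genes of G2 and mitosis, 16 fell and 0 rose, 17 and 0 adjusted over the list alone, with a median of -0.42 (camera adjusted p = 2.76e-07; adjusted p = 0.241 with an estimated correlation). They included the cyclin genes CCNA2 (-1.38) and CCNB1 (-0.88), KIF20A (-1.31) and DLGAP5 (-1.23). With the beta-actin covariate CCNB1 (-0.95), KIF20A (-1.30) and DLGAP5 (-1.27) did not pass (limma adjusted p = 0.0934, 0.0697 and 0.106). Cholesterol synthesis genes fell as well: 15 of 18 fell and 0 rose, the same adjusted over the list alone, with a median of -0.998 (camera adjusted p = 1.10e-09; adjusted p = 0.154 with an estimated correlation). INSIG1, a sterol sensor (-2.40), HMGCS1 (-2.05), LSS (-1.94) and NSDHL (-1.78) had the largest falls among them. The beta-actin 3' minus 5' difference was higher by 0.35 in the samples where these groups were lower.

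Genes of cell adhesion and the surrounding matrix were mostly higher in shFRY cells. Among 19 integrin and focal adhesion genes, 13 rose and 0 fell, the same adjusted over the list alone (median 0.47, camera adjusted p = 9.65e-06; adjusted p = 0.154 with an estimated correlation). ITGA10 (1.42) and ITGA3 (1.02) rose. ITGB3 (4.45) and ITGB4 (1.16) also passed, with 3 of 7 and 4 of 5 probe sets called higher and 0 called lower. Without _s_at and _x_at probe sets another probe set stood for each, at -0.03 and -0.18. The only probe set of ITGA3 is of the _s_at kind. Among 19 proteases and inhibitors of matrix turnover, 11 rose and 1 fell, 12 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 0.000353; adjusted p = 0.154 with an estimated correlation). The urokinase gene PLAU (3.001) and its receptor gene PLAUR (2.50) rose with the stromelysin genes MMP10 (2.23) and MMP3 (1.70). Among 26 genes of the extracellular matrix and basement membrane, 13 rose and 1 fell, the same adjusted over the list alone (median 0.40, camera adjusted p = 0.000467; adjusted p = 0.154 with an estimated correlation). FN1, which encodes fibronectin (3.12), COL12A1 (2.56) and COL4A1 (2.47) rose. COL3A1 fell (-1.82), and was at 0.39 without _s_at and _x_at probe sets.

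EGF family genes and genes of ERK output were mostly higher in shFRY cells, and other signalling lists were mixed. Of 13 genes for EGF family ligands and receptors, 10 rose and 2 fell, the same adjusted over the list alone (median 0.63, camera adjusted p = 0.00187; adjusted p = 0.154 with an estimated correlation). The ligand genes HBEGF (4.10), EREG (2.53) and TGFA (1.43) rose, and the receptor gene ERBB3 fell (-1.83). With the beta-actin covariate TGFA was at 0.94 and ERBB3 at -1.63, and neither passed (limma adjusted p = 0.0927 and 0.0902). Of 18 genes of ERK output and feedback, 12 rose and 3 fell, the same adjusted over the list alone (median 0.70, camera adjusted p = 0.000467; adjusted p = 0.154 with an estimated correlation). The ERK phosphatase genes DUSP5 (3.21) and DUSP6 (1.49) and the immediate early gene FOS (1.82) rose, while the feedback inhibitor gene SPRY1 fell (-2.03). Of 19 genes of the TGF-beta and BMP response, 8 rose and 4 fell, 10 and 4 adjusted over the list alone (median 0.25, camera adjusted p = 0.0314; adjusted p = 0.241 with an estimated correlation), with rises of the ligand genes BMP2 (4.64) and INHBA (3.15), the pseudoreceptor gene BAMBI (3.56) and TGFBI (1.93). This list missed the threshold without shFRY sample 3 (camera adjusted p = 0.0591). Of 21 YAP and TAZ target genes, 10 rose and 4 fell, the same adjusted over the list alone (median 0.26, camera adjusted p = 0.0306; adjusted p = 0.167 with an estimated correlation). RBMS3 (2.67) and GADD45A (2.23) rose, whereas IGFBP3 (-2.51) and CCN2 (-1.42), a widely used YAP reporter, fell. Of 23 genes of the NDR and LATS kinase pathway, in which FRY acts, 9 rose and 4 fell, 9 and 5 adjusted over the list alone, and the list did not pass (median 0.25, camera adjusted p = 0.373). LATS1 (0.92) and LATS2 (0.78) rose, and TEAD3 (-0.95) and NF2 (-0.82) fell. With the beta-actin covariate LATS2 (0.96), TEAD3 (-0.86) and NF2 (-0.97) did not pass (limma adjusted p = 0.0678, 0.0986 and 0.0592).

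Basal markers passed as higher in shFRY cells, and luminal markers passed as lower with a median near 0. Of 19 basal and myoepithelial markers, 9 rose and 3 fell, 10 and 3 adjusted over the list alone (median 0.42, camera adjusted p = 0.00624; adjusted p = 0.241 with an estimated correlation). The basal keratin gene KRT14 rose from 7.89 ± 0.16 to 10.81 ± 0.06 (SD, n = 3 each; log2 fold change 2.92), LAMB3 (1.71) and the oxytocin receptor gene OXTR (1.35) rose, and TRIM29 fell (-1.38). Of 21 luminal mammary markers, 9 fell and 2 rose, the same adjusted over the list alone (median -0.03, mean -0.54, camera adjusted p = 0.0314; adjusted p = 0.293 with an estimated correlation). Over the upper part of probe sets by mean, the median of the measured luminal markers was -0.58 (camera adjusted p = 0.0285). AGR2 (-5.10), the epithelial transcription factor gene ELF3 (-2.30) and MUC1 (-1.87) fell, and XBP1 (1.98), which is also a member of the unfolded protein list, rose. Of 22 mesenchymal markers, 10 rose and 4 fell, 14 and 4 adjusted over the list alone (median 0.36, camera adjusted p = 0.00819; adjusted p = 0.154 with an estimated correlation), with rises of POSTN (3.47), FN1 (3.12) and LOX (1.93) and a fall of the proteoglycan gene DCN (-2.79). Of 17 genes of milk and secretory differentiation, 5 rose and 1 fell, 6 and 1 adjusted over the list alone (median 0.23, camera adjusted p = 0.0101; adjusted p = 0.154 with an estimated correlation). The members that rose most, LCN2 (4.01), XDH (3.27), WFDC2 (2.52) and LTF (1.02), include the antimicrobial iron-handling proteins lipocalin-2 and lactoferrin, which are also made outside lactation. The epithelial junction genes did not pass as a list (7 rose and 5 fell of 24, 8 and 7 adjusted over the list alone, camera adjusted p = 0.734), although the tight junction gene CLDN1 rose (3.41), DSP rose (1.02), and CLDN4 (-1.36) and GRHL2 (-1.35) fell. Squamous differentiation genes did not pass either (8 rose and 4 fell of 27, 9 and 4 adjusted over the list alone, camera adjusted p = 0.321), with rises of S100A8 (4.69) and SPRR1B (3.06) and a fall of the kallikrein gene KLK5 (-2.96).

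**Figure D4:**
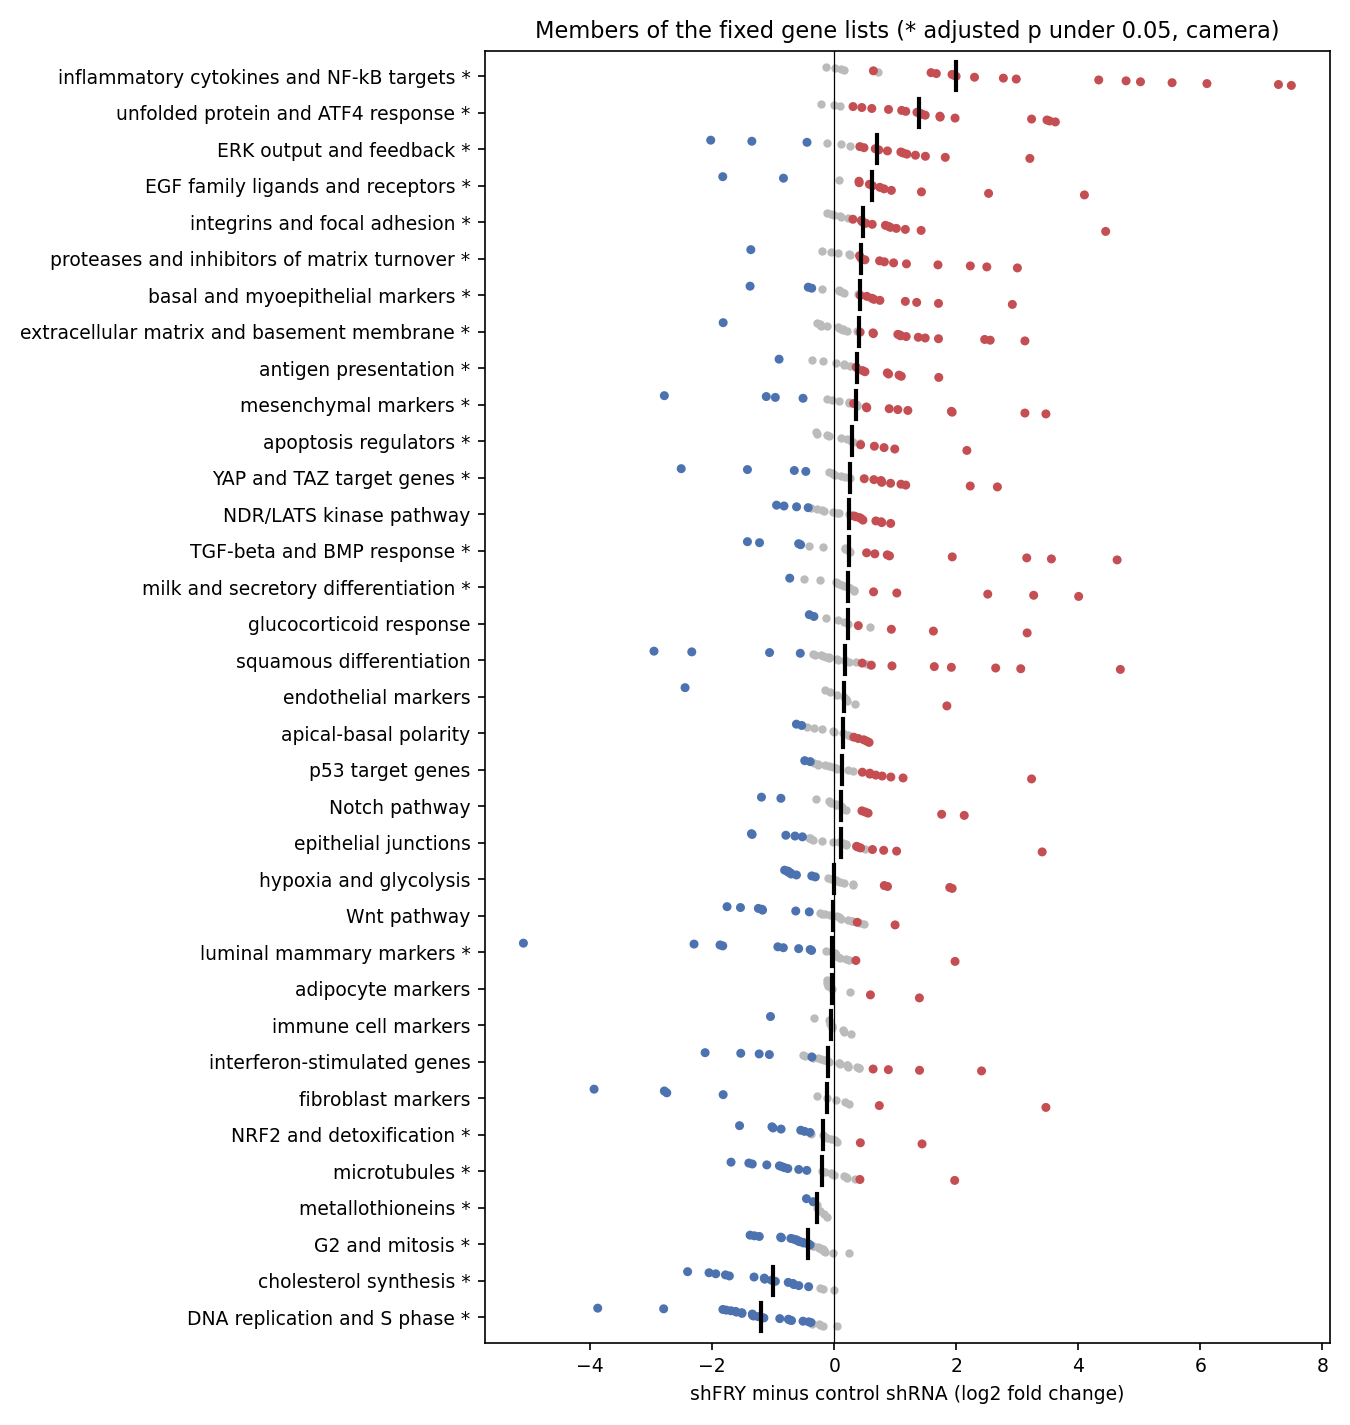
Log2 fold change (shFRY minus control) of each measured member of the 35 gene lists; red and blue points passed an adjusted p of 0.05 as higher and lower, grey points did not, black bars are list medians, and asterisks mark the 21 lists past the threshold in camera. Inflammatory genes (median 1.997) lie farthest right and DNA replication genes (median -1.20) farthest left.

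Several tubulin genes were lower in shFRY cells. Of 21 microtubule genes, 10 fell and 2 rose, the same adjusted over the list alone (median -0.19, camera adjusted p = 0.00443; adjusted p = 0.180 with an estimated correlation). TUBB3 (-1.69), TUBB4B (-1.40) and TUBB (-1.34) fell, and the microtubule-associated protein gene MAP1B rose (1.97). Of 17 genes of NRF2 and detoxification, 7 fell and 2 rose, the same adjusted over the list alone (median -0.19, camera adjusted p = 0.0161; adjusted p = 0.154 with an estimated correlation). HMOX1 (-1.55), NQO1 (-1.02) and ABCC2 (-1.003) fell, and the cystine transporter gene SLC7A11, which ATF4 also controls, rose (1.44). With the beta-actin covariate ABCC2 was at -0.51 and did not pass (limma adjusted p = 0.432). Of 7 metallothionein genes 2 fell and 0 rose, the same adjusted over the list alone (median -0.28, camera adjusted p = 0.0300; adjusted p = 0.492 with an estimated correlation); these were MT1F (-0.46) and MT1G (-0.35), and MT1G was at 0.24 without _s_at and _x_at probe sets. The MT1G call was lost without any 1 of the control samples or without shFRY sample 1 or 2 (limma adjusted p = 0.0539 to 0.0847), and with the replicate number as a block (0.0573). Of 17 antigen presentation genes, 8 rose and 1 fell, 9 and 1 adjusted over the list alone (median 0.37, camera adjusted p = 0.00340; adjusted p = 0.237 with an estimated correlation), among them PSMB9 (1.71), TAP2 (1.10, with 1 of its 4 probe sets called in the other direction) and HLA-B (1.06), while CIITA fell (-0.90). The CIITA call was lost without any 1 of the control samples or without shFRY sample 2 or 3 (limma adjusted p = 0.0537 to 0.140), its difference was -0.58 without shFRY sample 3, and the mean of its probe sets was -0.15. With the replicate number as a block and with another quantile normalization CIITA did not pass either (limma adjusted p = 0.0795 and 0.0686). Of 14 apoptosis regulators, 5 rose and 0 fell, the same adjusted over the list alone (median 0.29, camera adjusted p = 0.0325; adjusted p = 0.180 with an estimated correlation); PMAIP1, which encodes the BH3 protein NOXA, rose most (2.17). Without _s_at and _x_at probe sets the antigen presentation, microtubule, NRF2 and apoptosis lists no longer passed camera, with adjusted p-values of 0.323, 0.0746, 0.0956 and 0.107 and medians of 0.13, -0.18, -0.16 and 0.32. The luminal, basal and YAP and TAZ lists did not pass there either, at 0.546, 0.0680 and 0.0680 with medians of 0.01, 0.14 and 0.20. The milk, NRF2 and metallothionein lists did not pass over brighter probe sets only (0.0625, 0.0919 and 0.0732, with medians of 0.36, -0.18 and -0.28). The microtubule, luminal and metallothionein lists did not pass with the beta-actin covariate (0.0503, 0.134 and 0.257, with medians of -0.22, -0.10 and -0.19), nor the metallothionein list with the mean of each gene's probe sets (0.0536, median -0.23). Against random lists matched on expression, 8 of the lists past camera did not pass by their medians. These were TGF-beta and BMP, YAP and TAZ, and milk (adjusted p = 0.0541 each), apoptosis (0.0619), microtubule and metallothionein (0.152 each), NRF2 (0.240) and luminal (0.479). Besides the TGF-beta and BMP list, single samples decided 4 calls in camera: the YAP and TAZ list was at 0.0511 without shFRY sample 1, the luminal list at 0.0636 without control sample 1, the apoptosis list at 0.0506 and 0.0616 without shFRY sample 2 or 3, and the metallothionein list at 0.0636, 0.0581 and 0.0506 without control sample 1 or shFRY sample 1 or 2. The medians there were 0.33 for YAP and TAZ, -0.01 for luminal and 0.32 and 0.25 for apoptosis genes. For metallothioneins they were -0.22, -0.25 and -0.25.

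The remaining lists did not pass the threshold in camera. Interferon-stimulated genes went both ways, with 4 rises, led by ISG20 (2.41) and RIGI (1.40), and 5 falls, led by OAS1 (-2.12) and HERC6 (-1.53), among 30 (camera adjusted p = 0.587). Among 20 p53 target genes 8 rose and 2 fell (camera adjusted p = 0.0997), with SESN2 (3.23), GDF15 (1.13) and CDKN1A (0.78) among the rises. Among 11 glucocorticoid response genes 4 rose and 2 fell (camera adjusted p = 0.0564), with DUSP1 (3.16) and CEBPD (1.62) rising. Without control sample 3 or shFRY sample 1 this list passed, at 0.0481 and 0.0336. It also passed with quantile normalization, array weights and the beta-actin covariate, at 0.0397, 0.0484 and 0.0495. Wnt pathway genes had 7 falls, including FZD7 (-1.76) and DKK1 (-1.54), and 2 rises among 22 (camera adjusted p = 0.268), and Notch pathway genes had 5 rises, including HEY1 (2.13) and JAG1 (1.76), and 2 falls among 17 (camera adjusted p = 0.318). Hypoxia and glycolysis genes (4 rose and 8 fell of 20, camera adjusted p = 0.769, and 0.0461 as lower without _s_at and _x_at probe sets) and apical-basal polarity genes (5 rose and 2 fell of 15, camera adjusted p = 0.553) did not pass. Markers of other cell types did not pass either: for fibroblasts 2 rose and 4 fell of 11 (camera adjusted p = 0.334), for endothelium 1 rose and 1 fell of 9 (0.652), for adipocytes 2 rose and 0 fell of 7 (0.373), and for immune cells 0 rose and 1, PTPRC (-1.06), fell of 10 (0.679). PTPRC did not pass with the mean of its probe sets (-0.24, limma adjusted p = 0.0870) or with the beta-actin covariate (-0.24, 0.623). Adjusted over the list alone, 4 of the p53 targets fell in place of 2, and the counts of the other lists in this paragraph stayed as they were. The adipocyte list has a median of -0.04 and a mean of 0.27, and the hypoxia list a median of -0.01 and a mean of 0.06. Over the settings tried, the hypoxia median lay between -0.40 and 0.02. The fibroblast median was -0.12 in the main comparison and lay between -1.82 and 0.10 over the settings, and that list passed in 0 of them.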

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

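The tests of leukocyte markers, interferon-stimulated genes, clones, mitotic genes and scaling were chosen after the results they bear on had been seen, and so was the beta-actin covariate, after the beta-actin difference and the changes of the lists; the bound of that RNA quality test and the tests of neighbouring genes and splits of the samples were written before their own results were seen.

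Probe sets with no gene symbol listed, which the gene-level comparison does not use, also carried signal above the control samples: 579 of 11721 were higher in shFRY past the threshold of limma, and 879 were lower. The probe set with the largest rise among them, 1567703_at, went from 1.33 ± 0.13 to 8.84 ± 0.38 (SD, n = 3 each), a log2 fold change of 7.52 (limma adjusted p = 4.39e-07). Among the 1801 probe sets with several gene symbols, 197 were higher and 272 lower in shFRY.

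The comparison called 5889 genes, 1484 of them changed at least 2-fold, and 21 lists. Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave counts as large in each case, and the highest of the other 9 gave 0 genes, 0 genes changed at least 2-fold and 9 lists. Because 10 splits cannot give a share under 0.1, they are too few to judge chance.

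Inflammatory and ATF4 genes rose in shFRY. The beta-actin 3' minus 5' difference was used as a covariate for RNA quality. The group effect on the mean of the inflammatory list was then 2.80 (95% confidence interval 2.63 to 2.96) against 2.82 without it. That of the ATF4 list was 1.42 (1.07 to 1.76) against 1.47. A linear effect of this difference, alike in both groups, thus left most of the rise. The covariate correlated with the group at r = 0.85 over the 6 samples, and 3 residual degrees of freedom were left. Its SD was 0.03 in shFRY and 0.19 in control samples, so the slope rests mostly on the control samples. There CXCL1 (3.297), CXCL3 (3.43) and CXCL8 (3.35) had signals near the median of all probe sets (3.04). The covariate therefore cannot exclude RNA quality as a cause. Leukocytes in the cultures are argued against by a median of -0.0547 over 10 immune cell markers with 0 rises, the highest signals in shFRY (genes outside the naming rule) being CSF1R at 2.95, TYROBP at 2.87 and FCER1G at 2.74, below the median of all probe sets (3.04), and an interferon response to double-stranded RNA by a median of -0.10 over 30 interferon-stimulated genes with 4 rises. A technical difference that moved with the group stays open: the spikes bioB and bioC were higher by 0.49 and 0.46 in shFRY and were not adjusted for. A difference between 2 selected clones unrelated to FRY stays open too, because the design has 1 clone per construct. The same holds for an effect of the shRNA on other genes. FRY knockdown and clone cannot be told apart. That lower FRY may have raised these genes is a hypothesis which other clones would have to test.

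DNA replication genes fell in shFRY. With the beta-actin covariate the group effect was -1.11 (95% confidence interval -2.03 to -0.19) against -1.14 without it. A fall thus remained beyond a linear effect of this difference alike in both groups. The slope on the covariate was -0.07 (SE 0.69), too imprecise to tell how much RNA quality contributes, so it cannot be excluded as a cause. The list median was -1.17 (camera adjusted p = 2.71e-13) with median centring and -1.24 (6.31e-13) with another quantile normalization, against -1.20 as deposited. The sample medians already lay between 3.02 and 3.06, so both settings could change little. They show only that no large difference in scaling was left between the deposited samples, and do not test scaling before RMA. A shift shared by all genes that RMA removed is not visible here. A lower share of cycling cells was tested as a cause that lowers replication and mitosis genes alike. The medians of -1.20 and -0.42 differed by -0.78 (two-sided permutation of genes between the lists, p = 0.00111), so the lists did not fall alike. Genes are not independent replicates in that test. Different lists need not fall equally with fewer cycling cells, so the difference cannot decide on that cause. Some or all of the fall could still come from fewer cycling cells, since 16 of 29 mitotic genes fell as well and 0 rose. The difference between the clones stays open here too, because each construct had 1 clone. So does the difference of the spikes bioB and bioC, which was not adjusted for.

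Copy number differences between the clones were sought in runs of 41 neighbouring genes among 9875 expressed genes. The largest absolute median of a run was 0.39, under the 99th percentile of the largest run median in 1000 shuffles of gene order (0.49), so no run stood out. This argues against a copy number difference that shifts 41 neighbouring genes by more than 0.49; a smaller shift or a shorter segment, which compressed array values could hide, stays open.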

How the results depend on the processing

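The beta-actin covariate was chosen after seeing the data; all other alternatives were planned. The count of 5889 genes stayed within 1.5 times under 14 of 17 alternatives and went to 1026 with the beta-actin covariate (545 higher, 481 lower; 936 changed at least 2-fold, 441 of them lower), where the median SE rose from 0.12 to 0.23 and 99.8% of the 5889 genes kept their sign. It was 12617 over all probe sets and 3530 at an adjusted p under 0.01, and the 1484 genes changed 2-fold became 2905 with treat, a laxer test against a fold of 1.2. Leaving out 1 sample gave 4503 to 5766 genes. The 21 lists became 1 with an estimated correlation, where camera also has fewer degrees of freedom, and 13 with random lists. No clear pairing of the samples by the numbers in the titles was seen. Same-numbered deviations correlated at 0.003, -0.004 and 0.039, and only number 3 correlated best with its own number. These values over all probe sets, with 3 samples per group, cannot exclude a pairing that affects some genes. With the replicate number as a block 5330 genes and 21 lists passed; FRY probe sets 1555904_at (-0.49, limma adjusted p = 0.0263), 214319_at (-0.49, 0.0365) and FRY as a gene (-0.49, 0.0259) passed, and 204072_s_at (-0.75, 0.0522) did not. At 204072_s_at the covariate gave -0.38 (SE 0.35, limma adjusted p = 0.676) against -0.75 (SE 0.19), so both a smaller difference and a wider error ended the call. The mean of the FRY probe sets was -0.51 (limma adjusted p = 0.0146), whereas FRY as a gene did not pass in the main comparison (-0.49, limma adjusted p = 0.181). Leaving out 1 sample gave -0.62 to -0.37 at 1555904_at, -0.91 to -0.57 at 204072_s_at, -0.42 to -0.24 at 214318_s_at and -0.69 to -0.24 at 214319_at; 1555904_at passed without control sample 2 (limma adjusted p = 0.0357) and 214318_s_at without shFRY sample 3 (0.0345). Without _s_at and _x_at probe sets, COL3A1 (0.39), ITGB3 (-0.0259), ITGB4 (-0.18) and MT1G (0.24) turned sign through another probe set, and list directions turned, none past the threshold, for Notch (median -0.0755), fibroblasts (0.10) and epithelial junctions (-0.10). In camera's direction though not in the median they turned for endothelium without these probe sets (0.0206) and with mean probe sets (0.0330) and for hypoxia with the upper part by mean (median -0.0487) and without shFRY sample 2 (-0.000307), its only turn when 1 sample was left out (medians -0.0540 to -0.000198); the cause was not tested for these lists or for FRY under the block. Of 139 named genes other than FRY, 90 kept their call in every alternative, and of 2054 values 1984 were on the same side of the threshold, 66 fell short and 4 turned. Most of these 66 were values with the beta-actin covariate, also for genes named above without that setting. Signal near background limits FRY and other dim genes.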

Other observations

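The 17 gene families were set by their symbols after the largest changes and the lists had been seen, but no value of an aminoacyl-tRNA synthetase or ribosomal protein gene had been; genes in the next paragraph were chosen after their values were seen. Cytoplasmic aminoacyl-tRNA synthetase genes, several of them ATF4 targets, were higher in shFRY cells: 9 of 14 rose and 1 fell, against the share of all other genes that rose (Fisher's exact test, adjusted p = 0.000611 over 34 tests of 17 gene families and 2 directions). WARS1 (1.204), AARS1 (1.10) and SARS1 (1.10) rose most of these genes, which are outside the naming rule, and RARS1 fell (-0.46). Of 51 ribosomal protein genes 0 rose and 3 fell, with a median of -0.002. Rises were rarer than among all other genes (Fisher's exact test, adjusted p = 0.0140), and the test for falls did not pass (0.170). These genes thus changed little in either direction. Another test passed, for rises of dual specificity phosphatase genes (adjusted p = 0.0179), but the values of 4 of its members had been seen, so nothing is drawn from it. The other tests did not pass, among them falls of kallikreins (0.170), falls of HOX genes (0.902) and rises of genes with a CXCL symbol (0.260). Genes are not independent replicates in these tests, and the other genes were not matched on expression. Brighter genes were called more often: 2552 of 11859 genes were higher in shFRY over the upper part of probe sets by mean. Over all genes the number was 2718 of 19775. The numbers of rises and falls of synthetases and ribosomal protein genes were the same under median centring and another quantile normalization, except that 2 ribosomal protein genes fell under median centring. Both settings change these already normalized values little.

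CYP1A1 fell from 5.80 ± 0.41 to 2.61 ± 0.37 (SD, n = 3 each; log2 fold change -3.18, limma adjusted p = 5.87e-05) and AHRR (-2.50), TIPARP (-1.48) and CYP1B1 (-0.90) fell in shFRY cells; each is a known target of the aryl hydrocarbon receptor, but its targets were not tested as a group. Of 9 measured HOXC genes 5 fell, HOXC13 (-2.87), HOXC11 (-1.53), HOXC9 (-1.42), HOXC6 (-1.26) and HOXC4 (-1.06), while HOXC8 (-0.03), HOXC10 (-0.16), HOXC5 (0.23) and HOXC12 (0.14) did not pass. Among 14 kallikrein genes, KLK5 (-2.96), KLK6 (-2.65), KLK10 (-2.59), KLK7 (-2.34) and KLK8 (-1.59) fell and KLK4 rose (0.37). The rise of CXC chemokine genes was not general: of 14 with a CXCL symbol 4 rose, CXCL1 (7.49), CXCL3 (7.28), CXCL2 (6.11) and CXCL8 (5.54), and CXCL5 (0.01), CXCL6 (0.11) and CXCL10 (0.16) did not pass. Of 2 relatives with other symbols, PF4 rose (0.43) and PPBP (0.29) did not pass. Median centring and another quantile normalization again gave 5 falls among HOXC genes and among kallikreins and 4 rises among CXCL symbols, the second with 1 fall among these.

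Inflammatory factors that rise while replication genes fall may reflect a senescence-like state, a hypothesis tested on 3 genes. The values of LMNB1 and HMGB2 had not been seen when they were chosen, but that of CDKN1A had, so its rise is not independent support. LMNB1 fell by 1.63 (limma adjusted p = 0.000193) and CDKN1A rose by 0.78 (limma adjusted p = 0.00116), as such a state needs, but HMGB2 was at -0.15 (SE 0.10, 95% confidence interval -0.37 to 0.08, limma adjusted p = 0.314). This lies above -0.3, the bound set beforehand for no fall, by more than the SE, so the predicted fall of HMGB2 was not found. The 95% interval reaches past the bound, and how far past it a value had to lie was settled after the value was seen. With LMNB1 and CDKN1A as predicted and HMGB2 not, these 3 genes cannot decide on such a state.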
